A study of Mus musculus with 14 samples.

How the data were processed

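RNA from bone marrow and hypothalamus of male C57BL/6 mice was measured on 1-colour Agilent arrays. Per the labels' protocols, total RNA was purified with a miRNeasy kit and labelled with Cy3 by the Low Input Quick Amp kit. The array design, the scanner software, the background correction and the normalization tool are not given in the sources used here. There were 14 arrays, 1 for each of 14 conditions, and per the labels each array held RNA pooled from 3 mice. No condition had a second array.

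The authors deposited 1 table of log2 values with 151113 rows and 14 columns. The scale was read from the values, which ran from 1.13 to 18.76. All columns had a median of 4.96, and sorted columns differed by at most 0.01, so the deposited log2 values were already quantile normalized over the arrays of both tissues. They were not centred per probe. Quantile normalization gives every array the same distribution, so a change shared by most probes is removed, and each fold given here is relative to that common distribution. The direction of a ratio was not at issue, since each array carried 1 dye.

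The rows were 95364 custom probes, 55681 catalogue probes and 68 control rows. The files do not pair the probe IDs with genes, so gene symbols, the preset gene lists and the preset cell type markers could not be used, and no list was tested. The planned rule named the called gene symbols with the largest change in the same direction in every pair of the comparison, which for vehicle irradiation are the PBS pairs. It was applied to probes, limited to 2 IDs that rose and 2 that fell in a comparison. For the drugs at 0 Gy it was not followed, and smaller called changes were named. Those passed over include A_30_P01031210 (9.57 with amifostine), CUST_37270_PI428753551 (9.79 with CBLB502) and CUST_43206_PI428753551 (8.08 with nilestriol). Each of these was bright on that drug's unirradiated array alone, but this was not so for every probe passed over. A_55_P1953169 (8.775 with CBLB502) was passed over too and was high on the CBLB502 arrays of both doses. With CBLB502 it read 13.9 at 0 Gy and 12.82 at 8 Gy. The PBS i.p. and i.g. arrays read 5.4 and 4.85 at 0 Gy, and 9.55 and 8.65 at 8 Gy. Control rows Mouse-GAPDH and Mouse-PGK1 carry a gene in their ID, and these 4 probes (3' and 5' ends of each gene) were kept with the array probes. The planned choice of 1 probe per symbol was void, and each probe was tested by itself.

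Probes were kept when they lay above the array's own 40th percentile (log2 3.95) on at least 2 arrays of the tissue. This left 100866 probes in bone marrow, 91776 in hypothalamus and 78835 in both. No detection flags were used here, so values near the lowest value of the table are read as dim, and the size of a fold against such a value is limited by that floor.

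Tests used limma 3.58.1 in R 4.3.3 with lmFit and eBayes(trend=TRUE) and Benjamini-Hochberg adjustment over the probes kept. A probe was called at an adjusted p under 0.05. Irradiation without a drug, each drug at each dose and each drug's effect on the irradiation response came from 1 fit of 8 cell means to the 10 bone marrow arrays. In that fit the PBS arrays given by injection (i.p.) and by gavage (i.g.) served as the 2 samples of vehicle at each dose, which left 2 residual degrees of freedom. A lone drug array was assumed to vary as the PBS arrays did. Irradiation over all 5 pretreatments was fitted with pretreatment as a block (4 residual degrees of freedom). The 4 hypothalamus arrays were fitted with pretreatment and dose (1 residual degree of freedom). The tissue difference was fitted on the 8 arrays of PBS i.p. and amifostine in both tissues (2 residual degrees of freedom). P-values therefore measure the spread between these arrays, not between animals. The number of arrays limits the precision.

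The size of the irradiation response was the slope through the origin of a pair's own log2 fold on the mean fold of the other 4 pairs, over probes called in those other 4 pairs. Scaling on spike-in RNA used the E1A probes, which bind the adenovirus RNA that Agilent's 1-colour kits add at known amounts. Those with a mean log2 value between 5 and 15 were used (6 probes in bone marrow, 5 in hypothalamus), and each array was shifted by their mean deviation.

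The simulation was rewritten after a first version gave more false calls than the test allows and recovered few changes, so both forms of its variances are given. The scripts were tested on simulated data in which 66 probes were changed 2-fold, 67 changed 4-fold and 67 changed 16-fold. With variances drawn from limma's fitted prior, the vehicle irradiation comparison recovered 2, 27 and 51 of them with 1 false call, and irradiation over 5 pretreatments recovered 9, 39 and 60 with 5 false calls. Amifostine at 8 Gy recovered 1, 16 and 45 with 2 false calls, and its effect on the irradiation response 0, 2 and 17 with 1. Irradiation in hypothalamus recovered 0, 19 and 58 with 3 false calls, and the tissue difference 0, 5 and 52 with 3. With each probe's own fitted variance in place of the prior, vehicle irradiation recovered 13, 46 and 62 with 37 false calls, and irradiation over 5 pretreatments 23, 51 and 62 with 12. Amifostine at 8 Gy recovered 14, 38 and 56 with 24 false calls, and its effect on the irradiation response 2, 29 and 54 with 31. Irradiation in hypothalamus recovered 40, 66 and 67 with 140 false calls, and the tissue difference 5, 46 and 63 with 60. How far a low count from the fits with 1 or 2 residual degrees of freedom reflects few changes thus depends on which variances hold, which these arrays do not settle. With each probe's own variance, false calls in every simulated comparison exceeded the share that an adjusted p under 0.05 allows. If those variances hold, a high count may also include more false calls than that threshold names. Far fewer probes were changed in the simulation than the 28660 called for vehicle irradiation. The Benjamini-Hochberg threshold depends on the share of changed probes, so neither the recoveries nor the rates of false calls carry over directly to comparisons with many calls.

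The comparisons, the filter, the tests and most alternatives were fixed before the data were examined. These alternatives were a 75th percentile shift, no filter, a 60th percentile filter, no intensity trend, a 2-fold threshold, left-out arrays or pairs, PBS of the same route only, and PBS route as a block. Cyclic loess, spike-in scaling, the 3 drug pairs alone, drugs averaged over both doses, drugs against each other and slopes on probes chosen in a PBS pair were added after seeing the data. Counts of the drugs against each other are not given as results, since each side had 1 array. All were 0 without the intensity trend and with any 1 PBS array left out. The counts of the drugs against PBS over both doses fell to 0 in the same way and are given with that limit. Gene list tests, the p53 list and the mean of probes per gene were not run.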

Results

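Expression of messenger and long non-coding RNA was profiled on 14 arrays from mice given a radioprotectant or phosphate-buffered saline (PBS) and then exposed to 8 Gy of gamma radiation or to 0 Gy. Tissue was taken at 12 h. In bone marrow, 10 arrays covered PBS i.p., PBS i.g., amifostine (10 mg/kg i.p., 0.5 h before), CBLB502 (0.2 mg/kg i.p., 0.5 h before) and nilestriol (150 mg/kg i.g., 48 h before), each at both doses. In hypothalamus, 4 arrays covered PBS i.p. and amifostine at both doses. Amifostine is a thiol prodrug, CBLB502 a flagellin-derived agonist of Toll-like receptor 5, and nilestriol a long-acting oestriol derivative. Each array held RNA pooled from 3 mice, and no condition was repeated. Values are deposited log2 values, and all folds are on the log2 scale. With no pairing of probe IDs to genes, results are given for probes.

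The first comparison asked what irradiation did to bone marrow without a drug. Of 100866 probes tested, 13283 rose and 15377 fell on the irradiated PBS arrays (28660 called by limma at an adjusted p under 0.05). The median size of the called changes was 0.99. Falls outnumbered rises among the large changes, with 407 probes at least 4-fold higher and 2240 at least 4-fold lower. Probe A_55_P2171221 rose by 6.63 (SE 0.389, limma adjusted p = 0.000324), from 1.69 and 1.44 at 0 Gy to 8.38 and 8.01 at 8 Gy. Probe A_51_P402160 rose by 5.95 (SE 0.370, adjusted p = 0.000434). Probe A_51_P232411 fell by 8.74 (SE 0.314, adjusted p = 0.000122), from 10.36 and 9.77 to 1.31 and 1.33, and probe CUST_18506_PI428753551 fell by 8.21 (SE 0.311, adjusted p = 0.000122). The dim side of these 4 changes lay near the lowest value of the table. Catalogue probes were called in 30.7% of 40076 and custom probes in 26.9% of 60786. The count was 0 without the dim filter, 1005 without the intensity trend, and between 0 and 720 with any 1 of the 4 PBS arrays left out. It was 32436 with PBS route as a block.

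**Figure D1:**
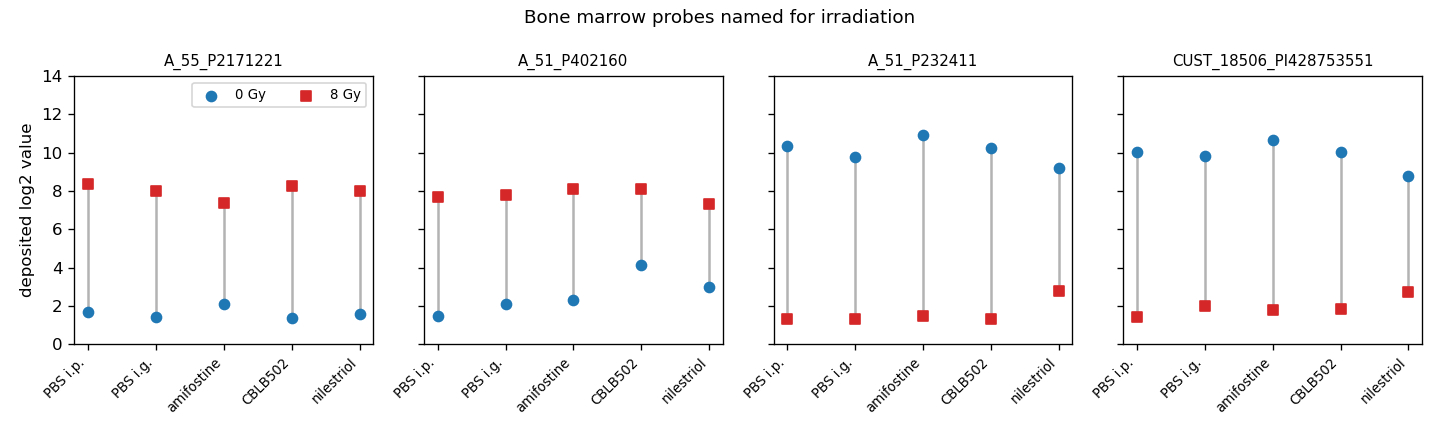
Deposited log2 value (vertical axis) of the 4 named probes on each bone marrow array, by pretreatment (horizontal axis), with circles for 0 Gy, squares for 8 Gy and lines joining the arrays of 1 pretreatment. Direction in the PBS pairs was part of the choice of probes, and the 3 drug pairs, which were not, moved the same way.

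The second comparison took the mean irradiation effect over all 5 pretreatments, with 1 pair of arrays each. Here 10602 probes rose and 14627 fell (25229 called by limma, 4 residual degrees of freedom). The same direction was seen in all 5 pairs for 10099 of those that rose and 14063 of those that fell. The fit takes its error from the spread between these same pairs, so a call by itself favours 1 direction in all of them. A change of at least 2-fold in every pair was found for 834 probes that rose (395 catalogue and 439 custom) and 1755 that fell (740 catalogue and 1015 custom). Independent pairs would give 1.47 and 1.42, a product that treats all probes as equally variable, so variable probes alone can exceed it. The probes that rose 2-fold in every pair had a median level of 7.18 at 0 Gy and 8.97 at 8 Gy, and those that fell had 7.51 and 5.18. Among the 4 probes named above, A_55_P2171221 was higher by 5.31 to 6.91 in the 5 pairs, and A_51_P232411 lower, with pair folds from -9.46 to -6.39. With the PBS i.p. pair left out 12601 probes were called, and with the 3 drug pairs alone 7735.

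Both directions above are relative to the common distribution of the arrays. The 6 mid-range E1A spike-in probes lay 1.06 higher (SD 0.116 over probes) on the irradiated than on the unirradiated PBS arrays, and 6 of 6 were higher. Scaling to these probes shifted the median fold of all probes in the vehicle comparison to -1.08, and to -0.36 over 5 pretreatments. On that scale 343 probes rose and 55203 fell without a drug, and 211 rose and 3387 fell over 5 pretreatments. For Gapdh, a glycolytic enzyme often used as a reference, the 3' and 5' control probes rose by 0.38 (SE 0.0909, limma adjusted p = 0.0221) and 0.49 (SE 0.0989, adjusted p = 0.0136) without a drug, which became -0.66 and -0.55 on the spike-in scale. Neither was called without the dim filter, without the intensity trend or with any 1 PBS array left out. The Pgk1 probes were not called without a drug, at 0.25 (adjusted p = 0.133) and 0.31 (adjusted p = 0.142), which became -0.79 and -0.73 on the spike-in scale. Over 5 pretreatments limma called the Pgk1 probes, at 0.38 (adjusted p = 0.0387) and 0.44 (adjusted p = 0.0332). It called the Gapdh probes there too, at 0.35 (adjusted p = 0.0302) and 0.40 (adjusted p = 0.0225). None of these was called without the intensity trend, on the spike-in scale or with the PBS i.p. pair left out. The 4 probes named for irradiation kept their direction on both scales.

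**Figure D2:**
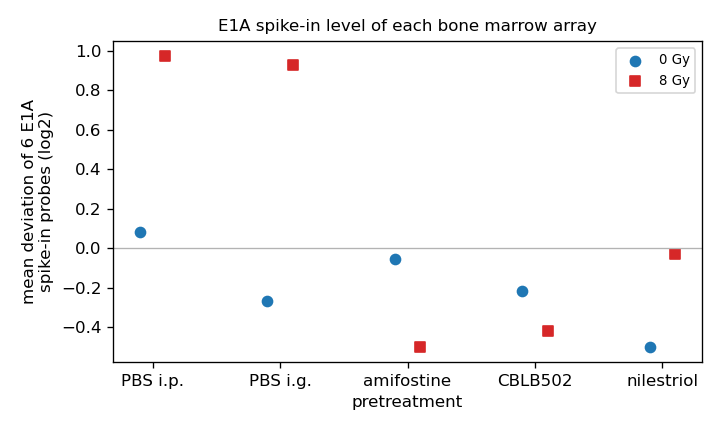
Mean deviation of 6 E1A spike-in probes from their mean over the bone marrow arrays (vertical axis, log2) for each pretreatment (horizontal axis), with circles for 0 Gy, squares for 8 Gy and 1 array per point. The irradiated PBS arrays lay at 0.97 and 0.93, and the other 8 arrays between -0.50 and 0.08.

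The drugs without irradiation were compared with the PBS arrays at 0 Gy. The probes named below are not those with the largest called changes. The amifostine array differed in 5 probes (2 higher, 3 lower), the CBLB502 array in 11 (9 higher, 2 lower) and the nilestriol array in 2 (both higher), by limma with 1 array per drug. At an unadjusted p under 0.05 the counts were 5196, 3947 and 8284, where 5043.3 would be expected by chance. CUST_77046_PI428753551 fell with amifostine by 3.5 (SE 0.237, limma adjusted p = 0.0316). Probe A_52_P318673 rose by 2.69 with CBLB502 (SE 0.173, adjusted p = 0.0149). CUST_92359_PI428753551 rose by 4.37 with nilestriol (SE 0.219, adjusted p = 0.00631). On 3 of the 5, 7 of the 11 and 2 of the 2 called probes the drug array lay at least 2-fold beyond all other 9 bone marrow arrays. No probe was called for any of the 3 drugs without the intensity trend, or with either unirradiated PBS array left out. Without the dim filter the counts were 0, 312 and 168.

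The drugs before irradiation were compared with the irradiated PBS arrays. The amifostine array differed in 13213 probes (6216 higher, 6997 lower), the CBLB502 array in 3070 (1539 higher, 1531 lower) and the nilestriol array in 21 (19 higher, 2 lower), all by limma in the same fit with 1 array per drug. A difference of at least 4-fold was called for 1800 probes with amifostine (792 higher, 1008 lower) and for 440 with CBLB502 (355 higher, 85 lower). The array of the drug lay 2-fold beyond all other bone marrow arrays for 2.42% of the amifostine probes and 6.42% of the CBLB502 probes, against 66.7% of the nilestriol probes. The 3' control probe of Gapdh was 0.54 higher with amifostine (SE 0.111, limma adjusted p = 0.0316) and that of Pgk1, another glycolytic enzyme, 0.62 higher (SE 0.140, adjusted p = 0.0364). The 5' probes of the same genes were not called, at 0.27 (adjusted p = 0.154) and 0.32 (adjusted p = 0.231). All 4 probes were higher on the spike-in scale, which adds 1 amount to every fold of a comparison. The median fold of all probes with amifostine moved from 0.075 to 1.53, so most directions on that scale follow from this amount. On that scale 67647 probes were higher and 345 lower with amifostine, 65545 and 69 with CBLB502, and 41368 and 21 with nilestriol. All 3 counts were 0 with either irradiated PBS array left out and 0 without the intensity trend. Without the dim filter they were 0 for amifostine, 128 for CBLB502 (122 higher, 6 lower) and 418 for nilestriol (410 higher, 8 lower). Against the PBS i.p. array alone they were 1206 for amifostine (157 higher, 1049 lower) and 73 for CBLB502 (28 higher, 45 lower).

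Averaged over both doses, with 1 array per drug and dose and the spread taken from the PBS arrays alone, limma called 4235 probes between amifostine and PBS (1484 higher, 2751 lower), 19 between CBLB502 and PBS, and 40 between nilestriol and PBS (36 higher, 4 lower). Of these, 507 amifostine probes differed at least 2-fold in the same direction at both doses, 46 higher and 461 lower. For CBLB502 there were 7 such probes and for nilestriol 25 (22 higher, 3 lower). All 3 counts over both doses were 0 without the intensity trend and 0 with any 1 PBS array left out. They were 0, 311 and 457 without the dim filter, and 8683, 310 and 810 with the 60th percentile filter. On the spike-in scale 46977 probes were higher and 735 lower than PBS with amifostine over both doses, 48634 and 48 with CBLB502, and 39010 and 35 with nilestriol.

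The test of each drug's effect on the irradiation response itself gave few calls. The fold at 8 over 0 Gy differed from that of PBS for 1 probe with amifostine, 7 with CBLB502 (2 higher, 5 lower) and 13 with nilestriol (12 higher, 1 lower). At an unadjusted p under 0.05 the counts were 15525, 20049 and 5327, against 5043.3 expected. The amifostine probe, A_30_P01020596, read 15.49 on the irradiated amifostine array and 8.27 or less on the others. For 12 of the 13 nilestriol probes, 1 nilestriol array lay at least 16-fold above all 9 others, as it did for 3 of the 7 CBLB502 probes. On the spike-in scale 51082 probes were called for amifostine (51042 higher, 40 lower) and 32915 for CBLB502 (32830 higher, 85 lower). All 3 counts were 0 without the intensity trend, 0 without the dim filter and 0 with any 1 PBS array left out.

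The irradiation folds of the 5 pretreatments were compared across probes, each pair of arrays being separate from the others. Probes are not independent replicates, so these correlations describe the arrays. The PBS i.p. and i.g. folds correlated at r = 0.59. Nilestriol correlated with them at 0.55 and 0.60. Amifostine correlated with them at 0.43 and 0.27, and CBLB502 at 0.39 and 0.21, while amifostine and CBLB502 correlated with each other at 0.69. Over 34890 probes changed at least 2-fold in the PBS i.g. pair, the slope on that pair's folds was 0.47 in PBS i.p., 0.45 with nilestriol, 0.20 with amifostine and 0.17 with CBLB502. Over 20656 probes chosen in the PBS i.p. pair it was 0.58 in PBS i.g., 0.45 with nilestriol, 0.38 with amifostine and 0.35 with CBLB502. Choosing probes on 1 pair lowers every such slope, so only the slopes beside each other compare.

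The size of the response against the other 4 pairs was 0.96 for PBS i.p., 0.97 for PBS i.g., 0.88 for amifostine, 0.78 for CBLB502 and 0.76 for nilestriol. The same direction as the other 4 pairs was seen in 99%, 95.6%, 95.0%, 89.1% and 94.0% of the probes used. Each slope used its own set of 12601 to 24004 probes and its own reference pairs, so the slopes do not compare strictly. The PBS slopes had an SD of 0.0048, but each held the other PBS pair in its reference. That SD gives no spread for the drug slopes. The PBS i.p. and i.g. folds themselves had SDs of 0.97 and 1.14 over probes. The slopes were not tested. On the spike-in scale the slopes were 1.17, 1.23, 0.54, 0.65 and 0.77 in the same order.

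**Figure D3:**
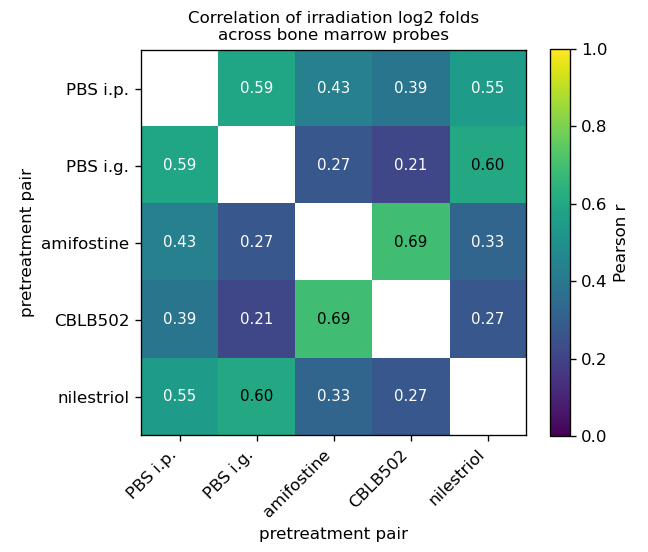
Pearson r across 100866 probes between the irradiation folds (8 minus 0 Gy, log2) of each pair of pretreatments in bone marrow, both axes listing the 5 pretreatments. The highest value was 0.69, between amifostine and CBLB502, and the lowest 0.21, between PBS i.g. and CBLB502.

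In hypothalamus, limma called no probe for irradiation (0 of 91776, with 1737 at an unadjusted p under 0.05 and 4588.8 expected). The control probes of Gapdh and Pgk1 had folds from -0.04 to 0.19 with an adjusted p of 0.998. The fold of PBS had an SD of 0.491 over probes and that of amifostine 0.304, and the 2 folds correlated at r = -0.08. Between amifostine and PBS 2 probes differed. A_55_P2035038 rose by 2.85 (SE 0.114, limma adjusted p = 0.0195), with 14.14 and 13.98 on the PBS arrays and 17.06 and 16.77 on the amifostine arrays. CUST_19396_PI428753551 fell by 4.32 (SE 0.137, adjusted p = 0.0103), from 16.07 and 15.60 to 11.70 and 11.33. At an unadjusted p under 0.05 there were 3637. After cyclic loess 5 probes rose with irradiation and none fell, and 34 rose and 4 fell with amifostine. On the spike-in scale 296 rose and 103 fell with irradiation, and 298 rose and 270 fell with amifostine. No probe was called for amifostine without the dim filter or without the intensity trend.

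The irradiation effect differed between tissues for 1651 of 78835 probes (492 more positive in bone marrow, 1159 more negative). The change was the larger one in bone marrow for 1639 of them, with a median size of 1.92 there and 0.14 in hypothalamus. The probes that fell at least 4-fold in bone marrow over 5 pretreatments (705 tested in both tissues) had median hypothalamus folds of 0.04 with PBS and -0.04 with amifostine. Above 0 were 52.8% of them with PBS and 39.4% with amifostine. Those that rose at least 4-fold in bone marrow (144) had medians of 0.20 and 0.14, and 64.6% and 67.4% of them were above 0. No share over all probes was set beside these. The count was 226 on the spike-in scale (13 more positive, 213 more negative), 0 without the dim filter, 149 without the intensity trend, and between 284 and 1047 with any 1 of the 8 arrays left out.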

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

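The tests of the spike-in probes, of a shared processing batch and of dose exchanges within pairs over 5 pretreatments were chosen after their results were seen.

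The effect of a drug on the irradiation response of bone marrow was called for 1 probe with amifostine, 7 with CBLB502 and 13 with nilestriol, which drew attention because the difference itself was tested. The irradiation effect differed between bone marrow and hypothalamus for 1651 probes, by the same kind of test. The 8 ways of exchanging the doses within pairs are too few for a share under 0.05. The real assignment gave 1651 probes, the highest other 1890, and 3 of the 8 gave at least as many. The other assignments with calls exchanged only hypothalamus doses. For irradiation over 5 pretreatments, the 16 ways of exchanging the doses within pairs are too few for a share under 0.05 as well. The real assignment gave 25229 probes and the highest other 1. The planned draw of 100 splits of the 10 arrays was run too, and its highest other gave 14908, but most of these splits ignore the pairs that the fit uses.

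The E1A spike-in probes, which enter the comparisons only through spike-in scaling, rose by 1.06 on the irradiated PBS bone marrow arrays. More E1A RNA alone is argued against only by the 7 ERCC and ETG control probes with a mean log2 value above 2.5. That needs RNA for those probes to have been added with the E1A RNA, which was not checked. Without it they do not bear on this question. These 7 probes rose by a median of 1.06 (7 of 7, and 0.10 to 0.56 between the PBS routes of a dose). In the drug pairs they moved by -0.32 with amifostine, -0.07 with CBLB502 and 0.73 with nilestriol. The 18 dimmer ones, at a median level of 1.54 near the floor, rose by 0.21, and all 25 by 0.43. The level of 2.5 was not part of the bounds written for this test. The 0.43 lay between those bounds, so the full set does not decide. Less labelled mouse RNA after irradiation in every pretreatment is argued against by the drug pairs, whose E1A probes moved by a median of -0.18 (nilestriol alone by 0.47). The ratio of the rises of the 7 brighter probes and the E1A probes was 1.002. Less mouse RNA in the irradiated PBS samples, or more of the control mix added to them, may give this rise, and these cannot be told apart with 1 labelling of each sample. No biological explanation was tested.

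The irradiated amifostine and CBLB502 arrays differed from the irradiated PBS arrays in 13213 and 3070 probes. Bins of brightness held a share of 0.0037 of the variance of the amifostine fold, but quantile normalization keeps this share small by itself, so a distortion by the normalization stays open. Isolated spots are argued against, since the amifostine array lay 2-fold beyond all other arrays for 2.42% of its probes. A processing batch shared by the irradiated amifostine and CBLB502 arrays could give the correlation of 0.69 between their folds, above the 0.59 of the PBS pairs, and stays open. An effect of the drugs predicts the same and stays open as well, untested, because each drug and dose had 1 array. The irradiated PBS arrays used as reference had spike-in deviations of 0.97 and 0.93, against -0.50 to 0.08 on the other bone marrow arrays. A difference in the handling of these PBS arrays would enter the counts of the drugs and of vehicle irradiation, and cannot be told apart here.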

How the results depend on the processing

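For the planned comparisons without a left-out array or pair, 60 combinations of comparison and setting stayed within 1.5 times the reported count. Of the others, 31 fell below and 20 lay above. The counts over both doses are not in this tally. With 1 left out, 4 stayed and 37 fell below. Of the 60, 14 stood under the 75th percentile shift, which moves nothing in a quantile normalized table and says nothing about stability. Others stood under the 2-fold threshold, which cannot move a count whose called probes all exceed 2-fold. That was so for the 5, 11 and 2 probes of amifostine, CBLB502 and nilestriol at 0 Gy, among others. The counts of the fits with 1 or 2 residual degrees of freedom held only in part. Without the dim filter the counts were 0 for vehicle irradiation, for amifostine at 0 and 8 Gy, for the 3 effects of a drug on the response, for amifostine in hypothalamus and for the tissue difference, and 312 and 128 for CBLB502 and 168 and 418 for nilestriol at 0 and 8 Gy. Without the intensity trend they were 1005 for vehicle irradiation, 149 for the tissue difference and 0 for each drug at each dose, the 3 effects of a drug on the response and amifostine in hypothalamus. The 60th percentile filter gave 43 and 8789 for CBLB502 at 0 and 8 Gy, 81 for nilestriol at 0 Gy, and 4 and 185 for the effects of amifostine and CBLB502 on the response. A 2-fold threshold gave 14100 for vehicle irradiation and 9121 over 5 pretreatments, by construction fewer. PBS of the same route gave 0 and 1206 for amifostine and 5 and 73 for CBLB502 at 0 and 8 Gy, and 3 for the CBLB502 effect on the response. Chosen after seeing the data, cyclic loess gave 5 for irradiation and 38 for amifostine in hypothalamus, and the 3 drug pairs alone gave 7735 over 5 pretreatments. Spike-in scaling, also chosen later, gave 55546 for vehicle irradiation, 3598 over 5 pretreatments, 8 and 67992 for amifostine, 65614 for CBLB502 at 8 Gy, 6 and 41389 for nilestriol, 51082 and 32915 for the effects of amifostine and CBLB502 on the response, 399 and 568 in hypothalamus and 226 for the tissue difference, with response sizes of 1.17 (PBS i.p.), 1.23 (PBS i.g.), 0.54 (amifostine), 0.65 (CBLB502) and 0.77 (nilestriol). It moved the Gapdh 3' and 5' and Pgk1 3' and 5' probes to -0.66, -0.55, -0.79 and -0.73 for vehicle irradiation, opposite to the direction without it. Over 5 pretreatments the 3' probes of Gapdh and Pgk1 moved to -0.034 (SE 0.327) and -0.00033 (SE 0.365), from 0.35 and 0.38. Their 5' probes moved to 0.020 (SE 0.318) and 0.060 (SE 0.355), from 0.40 and 0.44. These values on the spike-in scale over 5 pretreatments were smaller than their SE. Leaving out 1 array gave 0 to 720 for vehicle irradiation (720 without the irradiated PBS i.g. array), 0 to 0 for each drug at each dose and for the 3 effects on the response, and 284 to 1047 for the tissue difference (284 without the irradiated PBS array and 305 without the unirradiated PBS array of hypothalamus). Leaving out 1 pair gave 12601 to 24004 over 5 pretreatments, the lowest without PBS i.p. These fits have 1 degree of freedom fewer, and a lone PBS array is then assumed to vary as the others do. Apart from such construction, the cause was not tested. Leaving out a hypothalamus array leaves no spread for a test there. The mean of probes per gene, the gene list tests and the p53 list were not run, since the files do not pair probes with genes. Arrays were paired by pretreatment or PBS route only, as each group held 1 array. No background flags were used, so the signal over background behind dim probes is unknown.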

Other observations

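Of the tests in this part, the overlap of hypothalamus probes with bone marrow was chosen after its result was seen.

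Although no single probe was called for irradiation in hypothalamus, 92 probes were at least 2-fold higher in both hypothalamus pairs and 33 at least 2-fold lower, while 59 were higher with PBS and lower with amifostine and 59 the reverse. Independent pairs would give 13.6, 9.38, 6.83 and 18.6 in the same order, so all 4 classes exceeded this number and the excess is not particular to a shared direction. Of the 92, 90 were tested in bone marrow, on separate arrays. There 51 rose over 5 pretreatments and 3 fell, with a median bone marrow fold of 0.94, and 30 were at least 2-fold higher in all 5 bone marrow pairs. A small irradiation response shared by both tissues is a hypothesis for these probes. The 56.7% called higher lay above the highest of 1000 random sets matched on brightness (22.2%, median 10). Those sets were not matched on variability or on probes of 1 transcript, so they cannot exclude chance. The 56.7% missed the bound of 3 times the highest random share, which was written after the result was seen. With 1 array per condition the hypothesis stays open. The 22 probes lower in both hypothalamus pairs and tested in bone marrow showed no such overlap, with 4 called lower there and 2 higher.

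The irradiated PBS array of hypothalamus stood apart, with an SD of 0.491 against its unirradiated partner and 0.483 against the irradiated amifostine array, compared with 0.304 and 0.385 for the other differences. Its Gapdh 5' probe lay 0.37 below its 3' probe, with -0.79, -0.80 and -0.76 on the other arrays, while its Pgk1 difference went the other way, at -5.39 against -5.21, -5.27 and -5.09. Array noise without an irradiation response predicted no correlation of its fold with the mean bone marrow fold, and r was -0.065. The amifostine fold, which did not stand apart, had an r of 0.073. An irradiation response not shared with bone marrow predicts a value near 0 too, so this test cannot tell noise from such a response. The correlation describes the array as a whole and leaves the 92 probes above open. A biological difference of this pool of mice was not tested.

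Of the 25 probes at least 2-fold apart from PBS with nilestriol at both doses, 3 carry consecutive custom numbers. They were chosen after their values were seen. Over the unirradiated and irradiated arrays they were higher by 4.11 and 5.47 (CUST_92357_PI428753551), 4.29 and 5.47 (CUST_92358_PI428753551), and 4.37 and 4.72 (CUST_92359_PI428753551). Neighbouring custom probes may report 1 transcript. Over 44323 consecutive pairs the median correlation across the bone marrow arrays was 0.44, against -0.0044 for random pairs. Only 10.7% of consecutive pairs lay above 0.9, against 0.92% of random pairs. Counts of custom probes are thus likely larger than counts of transcripts, by an unknown amount.

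The fold of each drug at 0 Gy was set against the mean irradiation fold of the other drugs' pairs, which use separate arrays. Across probes r was -0.19 for amifostine, 0.06 for CBLB502 and 0.26 for nilestriol. Taken singly, CBLB502 had -0.07 with the amifostine pair and 0.17 with the nilestriol pair. Amifostine had -0.15 and -0.15, and nilestriol 0.23 and 0.25, with their other drug pairs. Of 7214 probes at least 2-fold apart from PBS with nilestriol alone, 67.3% lay on the side of the irradiation fold. The share was 49.0% of 4581 with CBLB502 alone and 37.6% of 6466 with amifostine alone. The unirradiated PBS i.g. and i.p. arrays were themselves at least 2-fold apart for 9341 probes, so these counts alone show no drug effect. The irradiated nilestriol array had 16 probes above log2 12 that lay at least 16-fold above all other bone marrow arrays, against 0 to 6 on each of the other arrays. Without the level of 12 it did not stand out, with 77 such probes against 102 and 137 on the irradiated PBS i.p. and i.g. arrays and 85 on the unirradiated PBS i.p. array.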
